A study of Mus musculus with 5 samples.

How the data were processed

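MicroRNA levels were compared on 5 microarrays of 2 channels each, on which total RNA of activated mouse T cells was set against RNA of T cells that had not been activated. The cells were CD4-positive and CD25-negative, the conventional helper T cells left when the CD25-positive population, rich in regulatory T cells, is taken away. Unactivated cells are called naive here, as in the title of the series. One array held cells activated overnight with the activated RNA in Cy5. Days 3 and 10 of activation each had 2 arrays of opposite dye, one with the activated RNA in Cy5 and the other with it in Cy3. Groups and dyes were taken from the labels. The means of activation and of culture are not given in the sources used here, and the labels do not say whether the 2 arrays of a dye pair held separate RNA extracts.

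The deposited table gives 1 log ratio for each of 178 probes on each array, with no missing value. Scanner signals, background, detection calls and the authors' normalization were not analysed here, and the scanner, the image analysis and the normalization are not given in the sources used here. The number of arrays limits the precision, and whether a probe was above background is unknown. The values are log ratios as deposited, with the log base and the numerator not given in the sources used here. The deposited values were read as log2 ratios, for which no earlier step is given in the sources used here, and every fold depends on that reading. Over the 171 microRNA probes, the deposited values of the 2 arrays of a dye pair correlated at r = -0.66 at day 3 and r = -0.43 at day 10, so the values run in 1 dye direction and had not been turned. Cy5 over Cy3, channel 2 over channel 1, was taken as that direction, which is likely rather than stated: it is the usual order for such tables, and it gives activated minus normal, the order in the array titles, on the 3 arrays with the activated RNA in channel 2. The ratios of the 2 arrays with the activated RNA in Cy3 were multiplied by -1. If Cy3 was the numerator, every direction given here is turned.

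The array medians of the turned log2 ratios, over microRNA probes, were -1.75 overnight, 0.20 and 1.42 at day 3, and -0.51 and -0.38 at day 10, so the arrays had not been centred on their medians. Values are given as deposited, and the main counts were repeated after each array was centred on its median. Centring takes off -1.75 overnight, 0.81 from the day 3 means and -0.45 from the day 10 means, and it takes off -1.26 from the difference of day 10 and day 3. A GEO annotation table gave 1 gene for 61 probes, several for 1 probe and none for the remaining 116. The number in the probe ID was that of the annotated gene in all 61, and number and letter were the same in 58. By gene ID, 50 of the 61 matched a current mouse symbol in the GRCm38.p6 table. Probes without a single annotated gene are given by probe ID. For the lists of microRNAs the number in the ID was read as the microRNA's number, and an alternative used annotated probes alone. The 7 probes for transfer RNAs and small nuclear RNAs were kept out of all counts and tests.

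For the comparison over all times, the 2 arrays of a pair were averaged, giving 1 value per time, and the 3 values were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg threshold 0.05). Naive RNA was the control on every array, so this test leaves out the spread of the control. Within a time no test was used, since a dye pair may be 1 pair of extracts. A probe counted as higher or lower where its mean log2 ratio was at least 1 from 0 (2-fold) with the same sign on both arrays, and between days 10 and 3 where the means differed by at least 1 and the 2 pairs did not overlap. The alternative was limma over the 5 arrays with a term per time and a dye term. Its adjusted p-values measure only the spread between arrays, which may be technical. Values given as ± after a pair mean are the distance of either array from that mean (n = 2 arrays). As the 2 arrays have opposite dyes, this distance is the size of the part that does not turn with the dye swap. It holds the probe's dye effect, which the mean cancels, and any offset of the arrays. It is therefore not a standard error, and a small ± does not show a more precise mean. Lists were tested over the 3 times with limma's camera (preset correlation 0.01, adjusted over 12 lists). At each time the list median was placed among the medians of 10000 random lists of the same size, without matching on expression.

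Before the data were examined, the 13 lists, the tests, the alternatives and the rule for naming probes were fixed. The rule took the 12 largest changes in each direction past the threshold over all times or, with fewer than 5 of these, the 8 largest with the same sign on all 5 arrays, then the 6 largest in each direction at each time and between days 10 and 3, and up to 4 members of each list, with miR-155 and miR-150 in every array. The list of myeloid and erythroid markers had 2 probes, under the minimum of 3 for a test. The tests were checked on simulated data. In 50 data sets of 171 probes simulated with the residual spread of the 5 arrays (SD 0.63) and probe-wise dye effects, the 3-value limma test recovered 98.9% of probes changed by 2 on the log2 scale, the dye-pair size rule 97.4% and the single-array size rule 86.8%. Among unchanged simulated probes these called 0.52%, 2.14% and 26.9%, rates that come from array spread and dye effects alone. Another simulation of unchanged cells let both pairs share 1 naive RNA, whose chance deviation was as large as the residual SD. There the dye-pair size rule called 27.0 probes higher and 27.2 lower at day 3, and 27.1 and 27.1 at day 10. With a simulated r of 0.40 between the 2 times, more of the simulated spread was separate to each time than shared. These counts therefore do not rest on the shared naive RNA alone. The real values spread far more between times than between arrays (SD 1.61), and with that spread the 3-value test recovered 24.8% of simulated probes changed by 2 and 88.6% of those changed by 4.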

Results

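The arrays followed mouse helper T cells from the unactivated state through activation overnight (1 array), for 3 days (2 arrays) and for 10 days (2 arrays), each set against naive cells on the same array. The question was how the microRNA profile of activated T cells differs from that of naive T cells. In total 171 microRNA probes and 7 probes for other small RNAs were measured on every array. After turning to activated over naive, the 2 arrays of the day 3 pair correlated at r = 0.66 across probes and those of the day 10 pair at r = 0.43, where probes are not independent replicates. Directions take Cy5 as the numerator, which is likely but not stated, and all would turn if it were Cy3.

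At day 3, 13 of 14 probes for microRNAs linked to lymphocyte activation were at least 2-fold higher in activated than in naive cells, and 7 of 10 for microRNAs of resting lymphocytes were at least 2-fold lower. The highest were probe 2org-210 (log2 ratio 5.03 ± 0.09), miR-31 (1org-31, 4.99 ± 0.69), probe 2org-214 (4.96 ± 0.44), miR-155 (1org-155, 4.88 ± 0.01), miR-212 (2org-212, 3.95 ± 0.37) and probe 1org-183 (3.87 ± 0.21). Probe 2org-210 carries the number of miR-210, known as a hypoxia-induced microRNA, and miR-155 is processed from the transcript of the Bic gene, which antigen receptor signals induce. The lowest were probes 1org-150 (-5.24 ± 0.61), 1org-181 (-4.53 ± 0.84), 1org-26a (-4.19 ± 0.25), 1org-7c (-3.66 ± 0.67), let-7g (1org-7g, -3.35 ± 0.55) and 1org-30b (-3.14 ± 0.56). Probes 1org-150 and 1org-181 carry the numbers of miR-150 and miR-181, known from mature and from developing lymphocytes. Centring takes 0.81 off each of these means and turned none of them, so that miR-155 stood at 4.07 and 1org-150 at -6.05. Across all microRNA probes, 65 were at least 2-fold higher and 22 at least 2-fold lower on average with the same sign on both arrays, and 26 and 34 after centring. The 22 lower, and the 26 higher after centring, were under the day 3 counts of simulated unchanged cells with a shared naive RNA. The number of calls in these cases therefore does not by itself show a change. The 65 higher, and the 34 lower after centring, were above the simulated counts.

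On the list of lymphocyte activation microRNAs none of the 14 probes was at least 2-fold lower at day 3, and after centring 12 were higher. The list median of 2.85 (2.04 after centring) lay at the 100th percentile of random lists. Besides the probes above these included 1org-132 (3.74 ± 0.35), without an annotated gene and numbered as miR-132, whose gene lies beside that of miR-212, and miR-21 (1org-21, 2.45 ± 0.37). The exception was probe 1org-146, at 0.70 ± 0.07 and at -0.11 after centring. All 5 probes of the miR-23/24/27 clusters, 3 of them also on the activation list, were at least 2-fold higher, with miR-23b (1org-23b) at 3.23 ± 0.10, miR-23a (1org-23a) at 2.58 ± 0.08, probe 1org-24 at 1.87 ± 0.43 and miR-27a (1org-27a) at 1.36 ± 0.21. After centring 4 of the 5 were higher and miR-27a was at 0.54. In the limma fit over 5 arrays, 13 of the 14 activation probes and all 5 cluster probes were higher at an adjusted p below the threshold, both over all probes and adjusted over the list alone. Of all 171 probes this fit called 67 higher and 22 lower at day 3, and 31 and 36 after centring.

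In the resting lymphocyte list at day 3, 7 of 10 probes were at least 2-fold lower and 1 was higher (miR-139, 2org-139, 1.04 ± 0.48, or 0.23 after centring), around a median of -2.07 (-2.88 after centring). Its lower members included 1org-142-s at -1.43 ± 0.62 beside 1org-150, 1org-181 and 1org-26a. Of the 9 let-7 probes, a family known for restraining growth, 6 were at least 2-fold lower: let-7b (1org-7b) stood at -3.07 ± 0.26, probe 1org-7a at -2.13 ± 0.24 and probe 1org-7f at -1.72 ± 0.18. Of the 6 miR-30 probes, 3 were lower, with 1org-30c at -2.53 ± 0.25 and 1org-30d at -2.24 ± 0.16, while 1org-30a was at -0.17 ± 0.55. Of the 4 miR-15/16 probes, 3 were lower, led by 1org-16 at -2.34 ± 0.65 and followed by miR-15a (1org-15a, -1.90 ± 0.19) and miR-15b (1org-15b, -1.45 ± 0.68), while miR-195 (1org-195) was at 0.69 ± 0.34. None of the 3 miR-29 probes reached 2-fold as deposited (-0.58 ± 0.59 for miR-29a, 1org-29a), and 2 were lower after centring (miR-29a at -1.39 and 1org-29c at -1.28). The fit over 5 arrays called 7 resting lymphocyte, 6 let-7, 3 miR-30 and 3 miR-15/16 probes lower, over all probes and adjusted over the list alone. Over the 4 lists, the medians lay at or below the 0.79th percentile of random lists.

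**Figure D1:**
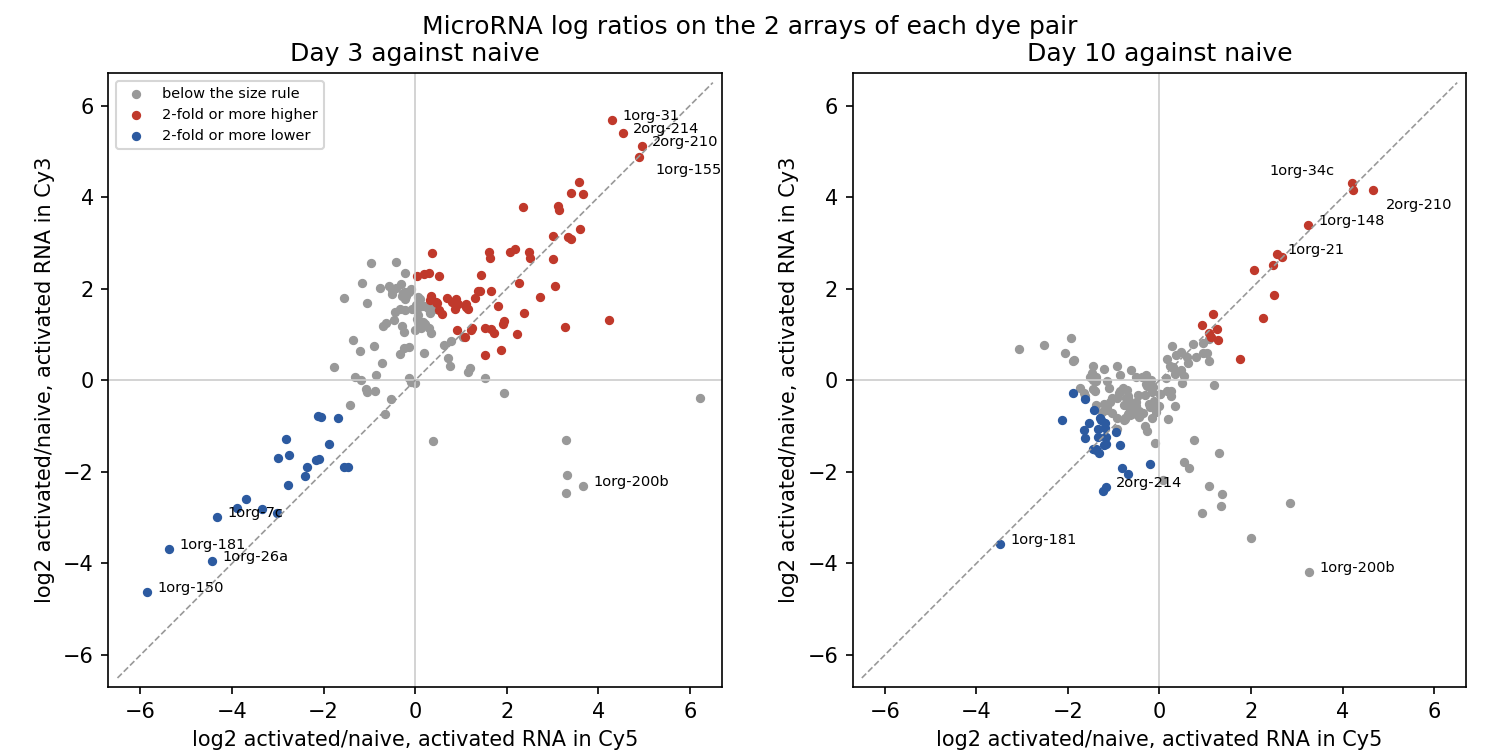
Log2 ratio of activated over naive RNA for 171 microRNA probes, with the array that held activated RNA in Cy5 on the x axis and the array that held it in Cy3 on the y axis, for day 3 (left) and day 10 (right). Red and blue points were at least 2-fold higher (65 at day 3 and 17 at day 10) or lower (22 and 29) with the same sign on both arrays, the dashed diagonal marks equal values, and 1org-200b lay far below it at both times.

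Lists of microRNAs known from other tissues had medians near that of the day 3 arrays, which was itself above 0. The medians were 0.91 for neural, 0.92 for stromal and muscle, 0.69 for epithelial and liver and 1.08 for embryonic stem cell probes, and after centring 0.10, 0.11, -0.12 and 0.27. In the same order 3, 5, 1 and 5 probes were at least 2-fold higher as deposited and none lower. The fit over 5 arrays called 3, 5, 2 and 6 probes of these lists higher and none lower, so its calls were not confined to the lymphocyte lists. After centring 1, 0, 0 and 0 were higher, and 1 epithelial and liver probe was lower. Examples before centring were probes 1org-124a (0.91 ± 0.72), 1org-145 (1.26 ± 1.06) and 1org-122a (1.06 ± 1.28), and miR-290 (1org-290, 0.71 ± 0.55). The myeloid probe 2org-223 was at -0.24 ± 1.12 and the erythroid miR-144 (1org-144) at 1.03 ± 0.50. Several other small RNA probes were lower: the histidine, alanine and methionine transfer RNA probes stood at -3.65 ± 0.04, -2.49 ± 0.09 and -1.91 ± 0.06, and the U6 small nuclear RNA probe at -2.20 ± 0.74. The proline transfer RNA probe was at -0.36 ± 0.70, and the remaining small nuclear RNA probes at 0.54 ± 0.46 and -0.06 ± 0.98. After centring the U6 probe was at -3.02 and the histidine transfer RNA probe at -4.46. Of the 65 probes higher at day 3, 26 were also at least 2-fold higher after centring, and of the 22 lower, 22. The day 3 counts also depended on the array used, with 110 probes higher without the array that held activated RNA in Cy5. That count comes from 1 array, with its dye effect not cancelled and no same sign on a second array required, so it is not under the same rule as the 65.

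At day 10, 17 probes were at least 2-fold higher and 29 lower than in naive cells, and 12 and 19 of these passed the fit over 5 arrays. The counts of 17 and 29 were under or near the 27.1 and 27.1 of simulated unchanged cells with 1 shared naive RNA. The number of calls at day 10 therefore does not by itself show a change. After centring 25 were higher and 7 lower, and without the array that held activated RNA in Cy3 27 were higher and 52 lower. The counts of 27 and 52 come from 1 array, with its dye effect not cancelled and no same sign on a second array required. With arrays brought to the same scale, 23 were higher and 53 lower at day 10 and 50 higher and 22 lower at day 3. That setting evens out the spread by construction, so it does not decide the source of the smaller number of calls at day 10. Probe 2org-210 (4.41 ± 0.25), miR-34a (annotated for 1org-34c, 4.26 ± 0.05), probe 2org-34 (4.19 ± 0.04), probe 1org-148 (3.31 ± 0.07), probe 2org-222 (2.68 ± 0.01) and miR-21 (2.66 ± 0.10) were the highest. MiR-34a is known as a target of p53, and its probe bears the ID of miR-34c while the annotation gives miR-34a. None of the probes named here for day 10 changed sign on centring. The lowest were probes 1org-181 (-3.52 ± 0.05), 2org-181b (-1.82 ± 0.59), 2org-214 (-1.75 ± 0.58), 2org-100 (-1.50 ± 0.62), 1org-7c (-1.48 ± 0.03) and 2org-182* (-1.46 ± 0.07).

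At day 10 the activation list still had more probes higher than lower. Of its 14 probes, 6 were at least 2-fold higher and 2 lower, 2org-214 and 1org-146 (-1.21 ± 0.14), around a median of 0.88 (1.33 after centring). In the fit over 5 arrays 6 were higher and 2 lower over all probes, and 7 and 2 adjusted over the list alone. MiR-155 was at 0.35 ± 0.12 and miR-31 at 0.54 ± 0.08. Of the miR-23/24/27 probes 3 were higher, among them miR-23a at 2.19 ± 0.32, and in the miR-17 clusters 2 of 11 (with 2org-17-3p lower, -1.20 ± 0.04), miR-18 (1org-18, 1.81 ± 0.44) and miR-19a (2org-19a, 1.05 ± 0.02). After centring 4 of the miR-23/24/27 probes were higher, and in the miR-17 clusters 6 were higher and none lower. Of the resting lymphocyte probes 4 of 10 were lower, of let-7 2 of 9, and of miR-30 1 of 6, while none of the miR-15/16 or miR-29 probes reached 2-fold. After centring 2 resting lymphocyte, 2 let-7 and 0 miR-30 probes were lower, and 1 let-7 and 1 miR-29 probe were higher. Probe 1org-150 was at -1.28 ± 0.05 (-0.84 after centring, under 2-fold), let-7b at -1.45 ± 0.13 and probe 1org-26a at -0.71 ± 0.06. The probe 2org-223 was at -1.44 ± 0.17. Of the 4 lists of other tissues, 1 stromal and muscle probe and 4 probes of each of the other lists were lower, and no probe of the 4 lists was 2-fold from 0 after centring.

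Between days 3 and 10, 22 probes were at least 2-fold higher at day 10 and 71 lower, with no overlap between the 2 pairs. After centring, which takes off the higher medians of the day 3 arrays, 48 were higher and 23 lower. The 22 higher and 23 of the 71 lower met the rule in both settings. The largest differences toward lower values were in probe 2org-214 (-6.71), miR-155 (-4.53), miR-31 (-4.45), miR-212 (-4.35), 1org-132 (-4.30) and 1org-298 (-3.95). Toward higher values they were in 1org-150 (3.96), let-7g (3.81), 1org-26a (3.48), 1org-148 (2.59), let-7i (1org-7i, 2.49) and miR-15a (2.41). Probe 2org-210 (-0.62), miR-21 (0.22) and 2org-222 (0.05) differed little between the 2 times as deposited, and by 0.64, 1.47 and 1.30 after centring. The size rule is no test, and separate cultures could not be compared. The fit over 5 arrays, whose adjusted p covers the spread between arrays only, called 15 probes higher and 75 lower at day 10 than at day 3, and 37 and 13 after centring.

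**Figure D2:**
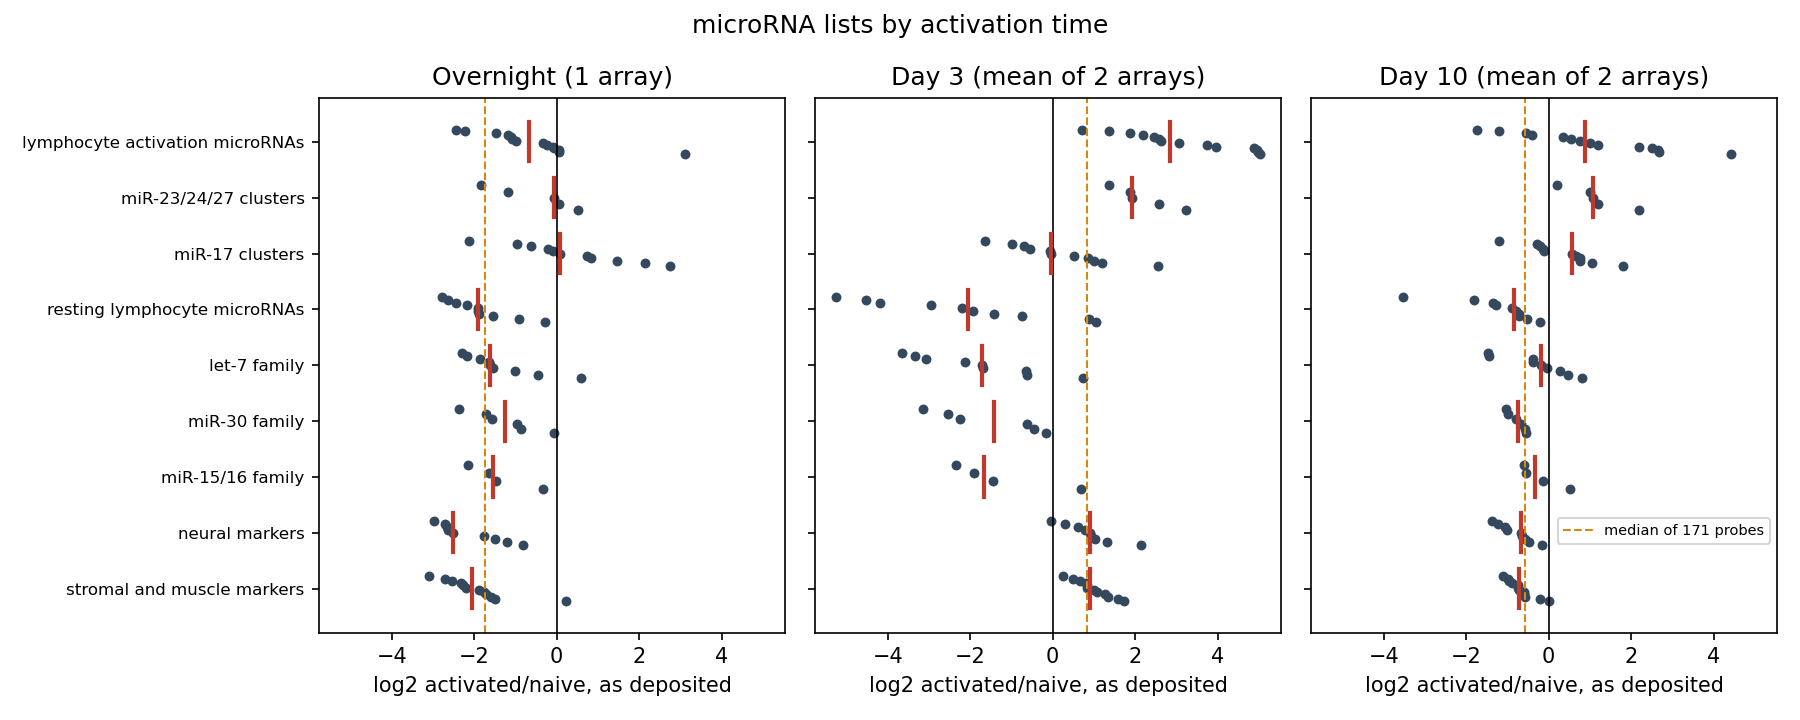
Log2 ratio of activated over naive RNA, as deposited and without centring, for the probes of 9 lists at each activation time, each dot a probe, red bars the list medians and the dashed line the median of 171 microRNA probes. At day 3 the median of the lymphocyte activation probes lay to the right of the line (2.85) and those of the resting lymphocyte and let-7 probes to its left (-2.07 and -1.72), while the medians of neural (0.91) and stromal and muscle probes (0.92) were near it.

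Overnight, 3 of the 7 probes at least 2-fold higher were of the miR-17 clusters, which are known from dividing lymphocytes. The highest were 2org-214 (log2 ratio 3.11), 2org-106 (2.75), 2org-17-5p (2.15), miR-20a (1org-20, 1.46), 2org-200c (1.42) and 1org-297 (1.24). Probe 1org-106a, read as the same microRNA as 2org-106 and counted beside it in the miR-17 clusters, was under 2-fold at 0.73. Of the 11 probes of the miR-17 clusters 3 were at least 2-fold higher and 1 lower (2org-17-3p, -2.14), and the list median of 0.08 lay at the 99.99th percentile of random lists. After centring 9 of the 11 were higher and none lower, with probe 1org-92 at 2.58, miR-20a at 3.20 and miR-18 at 1.12. With the dye effect measured in the 2 pairs taken off as well, a setting chosen after seeing the data, 8 were higher and none lower, with miR-18 at 0.32, and with the dye effect taken off but no centring 3 were higher and 3 lower. At day 3 the same list had 3 probes higher and 1 lower, around a median of -0.03, and after centring 1 higher and 4 lower, around -0.84. MiR-155 was at 0.05 and probe 1org-150 at -0.28 overnight, or 1.80 and 1.47 after centring. The lowest were miR-10a (2org-10a, -3.78), 2org-142* (-3.17), 2org-199a (-3.09), 2org-219 (-2.97), 1org-291-s (-2.87) and 1org-26a (-2.78). In all, 7 probes were at least 2-fold higher and 125 lower as deposited, and 37 higher and 7 lower after centring. In simulation the single-array size rule called 26.9% of unchanged probes, so the number of calls after centring does not by itself show a change. This was a single array without its dye swap, so these are values without a test, and their order depends on the dye effect. Once it was taken off, without centring, 2org-200c was at -0.94 and miR-10a at -2.80, and 2org-199a was no longer among the lowest probes. Then 1org-140 (-3.80) and 2org-224 (-3.40), named after their values were seen, were the lowest, against -2.11 and -0.79 as deposited. Their dye effects differed between days 3 and 10, at 0.61 and 2.77 for 1org-140 and at 3.31 and 1.92 for 2org-224, so these corrected values are uncertain.

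Taken over the 3 times as 3 replicates, no probe passed limma's test against 0 as deposited or after centring (smallest adjusted p = 0.48). As deposited the smallest adjusted p was 0.11, for 1org-181 (mean log2 ratio -3.20 ± 0.93, pooled SE, n = 3 times). Limma's moderation gave every probe this same SE, so it is not the spread of this probe's own 3 values. At an unadjusted threshold of 0.05 there were 3 probes higher and 8 lower (10 and 1 after centring), and without moderation across probes none after adjustment. With the 5 arrays as replicates and a dye term, 6 were higher and 4 lower. The same sign on all 5 arrays was found for 7 probes on the higher side and 18 on the lower, or 16 and 9 after centring. The former were miR-155 (mean 1.76), miR-23a (1.61), 2org-106 (1.57), 2org-17-5p (1.22), miR-19a (0.72), 1org-103 (0.48) and 2org-320 (0.33). Overnight as deposited, miR-155 (0.05), miR-23a (0.07), miR-19a (0.08) and 1org-103 (0.02) were near 0. With the dye effect taken off they were at -0.02, -0.05, 0.28 and 0.22, and after centring alone at 1.80, 1.81, 1.83 and 1.77. Probe 1org-106a, read as the same microRNA as 2org-106, had a mean of 0.17 and was not of the same sign on all arrays. The latter were led by 1org-181, 1org-26a (-2.56), 1org-150 (-2.27), 1org-7c (-2.26), 2org-142* (-2.01), 1org-142-as (-1.90), 1org-30b (-1.89) and miR-26b (1org-26b, -1.88). Without the overnight array 5 probes passed: 2org-210 (mean 4.72), 2org-34 (3.82) and miR-34a (3.67) were higher, and 1org-181 (-4.03) and 1org-150 (-3.26) lower.

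Among 12 lists tested over the 3 times with camera, 6 passed at the preset correlation. The activation list (mean 1.21, adjusted p = 3.7e-10), the miR-23/24/27 clusters (0.94, adjusted p = 0.0074) and the miR-17 clusters (0.30, adjusted p = 0.0497) were higher than the other probes. The resting lymphocyte list (-1.72, adjusted p = 6.3e-06), let-7 (-1.13, adjusted p = 0.028) and miR-30 (-1.19, adjusted p = 0.0497) were lower. None held with an estimated correlation (adjusted p = 0.43 for the activation, miR-17 cluster, resting lymphocyte and miR-30 lists and adjusted p = 0.58 for miR-23/24/27 and let-7). The miR-29 (adjusted p = 0.66) and miR-15/16 lists (adjusted p = 0.31) and those of neural, stromal and muscle, epithelial and liver, and embryonic stem cell markers (adjusted p from 0.42 to 0.64) did not pass. The activation, resting lymphocyte and miR-23/24/27 lists were the 3 that passed after centring, without the day 3 array with activated RNA in Cy3 and without the day 10 array with it in Cy3. The miR-17 clusters did not pass without the overnight array (adjusted p = 0.89). Adjusted over the list alone, 3 resting lymphocyte probes and 1 activation probe passed limma's test against 0.

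Across probes the day 3 and day 10 ratios correlated at r = 0.39 (rho = 0.28, covariance 0.73). In the simulation of unchanged cells, both pairs shared 1 naive RNA whose chance deviation was as large as the residual SD. It gave r = 0.40 and a covariance of 0.40, and that r also depends on the simulated spread separate to each time. Part of the relation may therefore rest on shared naive RNA, which could not be split here. Of the probes at least 2-fold higher, 15 were shared between the 2 times against 6.46 for independent lists, and of those lower, 6 against 3.73. Unchanged cells with 1 shared naive RNA gave 9.09 shared probes in each direction in simulation, from lists of about 27.1 probes. That value leaves out real effects and the one for independent lists leaves out the shared naive RNA, so the excess over either is not read as a shared effect. After centring the shared counts were 13 against 3.80 and 4 against 1.39. The overnight ratios correlated with those of day 3 at r = 0.11 and of day 10 at r = 0.10.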

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

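The checks on dye effects, on other-tissue probes overnight and on the correlation of days 3 and 10 were chosen only after the values had been seen, while centring and scaling of the arrays were planned. Among the 76 probes named by rule, 21 had both day 3 arrays on one side of 0 and both day 10 arrays on the other. The difference was not tested between separate cultures, and a tally of tests on probes picked for opposite signs would follow from that choice. Among all 171 microRNA probes, 49 had opposite signs in this way, and 29 after centring. Day 10 minus day 3 was -6.71 for 2org-214, -4.35 for miR-212, -4.30 for 1org-132, -3.95 for 1org-298, -3.68 for 1org-292-as and -3.64 for 1org-297. It was -2.35 for 1org-205, -2.33 for 1org-291-s, -2.25 for 1org-125b, -2.12 for 1org-1d, -2.04 for miR-143, -2.02 for miR-290, -1.92 for 1org-124a, -1.91 for 1org-146, -1.64 for 1org-291-as and -1.36 for 1org-141. In the opposite sense it was 0.79 for miR-20a, 1.35 for 1org-29c, 2.41 for miR-15a, 2.49 for let-7i and 3.81 for let-7g. As deposited, miR-20a was near 0 at day 3 (mean -0.03), so its sign there carries little. After centring 12 of the 21 still had opposite signs, among them 2org-214, 1org-132, miR-15a, let-7g and let-7i. The array medians account for -1.26 of each difference: after centring it was -5.46 for 2org-214, -3.05 for 1org-132, -1.09 for 1org-205, -0.86 for 1org-1d and -0.66 for 1org-124a.

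The spread of the ratios was larger at day 3 (SD 1.71 across probes) than at day 10 (SD 1.09). With arrays brought to the same scale, 50 probes were higher and 22 lower at day 3 and 23 and 53 at day 10, but that setting evens out the spread by construction. The correlation of the 2 times (upper end of its bootstrap interval 0.52, against a ceiling of 0.69 from the dye pairs) does not change with scale and decides nothing about it. A difference in scale between the arrays and the length of activation, which the design names, therefore cannot be told apart as sources of the larger spread, and each time may be 1 culture.

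The overnight array was below 0 for 86.5% of microRNA probes, with a median of -1.75. Probe-wise dye effects, measured in the pairs as the part that does not turn with the dye swap, correlated at r = 0.76 between days 3 and 10 across microRNA probes, which is consistent with dye effects tied to the probe. For 1org-200a, 1org-200b and 2org-200c the lowest of the 6 values was 2.05, but these probes were picked for being above 0 in the deposited values on all 5 arrays, so that value decides nothing further. Dye effects as measured in the pairs do not account for the overnight shift, since the median was still -1.42 after they were taken off. The overnight array had no dye swap, so a dye effect of its own was not measured and is not excluded. Without the 3 miR-200 probes, left out for their dye effects, 39 other-tissue probes lay at a median of -2.13 overnight, and all 42 at -2.07. Both are close to the array median, as a shift of the whole array would give. Not every probe for other small RNAs lay there. The alanine transfer RNA probe (-1.94) and small nuclear RNA probes at -1.66 and -2.02 did. The histidine (-1.20) and methionine (-1.18) transfer RNA probes were less low, and the proline transfer RNA (-0.07) and U6 (0.36) probes were near 0 or above it. Whether labelling, normalization or a true loss of most microRNAs relative to the reference moved the array stays open, and so does whether the centred or the deposited overnight values are nearer to the cells, as no signal intensities were analysed here.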

How the results depend on the processing

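No paired analysis was possible because the labels do not pair arrays across the times. No value was missing, so the alternative on missing values gave nothing to run. Counts are higher then lower probes. Centring each array gave 37 and 7 overnight, 26 and 34 at day 3, 25 and 7 at day 10, and 48 and 23 for day 10 against day 3. No probe called both as deposited and after centring or scaling turned its direction, but this says nothing about robustness. The shifts made by centring are too small to turn a 2-fold call into one of the other direction. Scaling keeps the sign of every ratio, so no call within a time could turn. Bringing arrays to the same scale gave 3 higher overnight, 53 lower at day 10, and 1 and 1 over the 3 times (2org-210 and 1org-181). Leaving out probes whose dye pairs disagreed by more than 1 kept 70 probes and gave 3 and 42 overnight, 41 and 11 at day 3, 6 lower at day 10, and 14 and 30 between the days, as fewer probes were counted. The 1.5-fold rule gave 14 higher overnight and 66 lower at day 10. Limma over 5 arrays with a dye term gave 3 and 66 overnight and 6 and 4 over the 3 times, where each array counts as a replicate and the lone overnight array is assumed to vary like the others. Without a dye term it gave 0 and 0 overnight, 38 higher at day 3, 9 and 1 at day 10, 3 and 9 between the days, and 1 and 1 over the 3 times. Using only the 2 dye pairs gave 3 and 2 over the 3 times. Chosen after seeing the data, taking off the dye effect and centring gave 27 and 13 overnight, and taking off the dye effect moved 2org-200c overnight from 1.42 to -0.94. Of 12 lists, 6 passed in camera, against 0 with an estimated correlation, 0 with fry, and, chosen after seeing the data, 3 after centring and 2 with annotated probes alone. Leaving out 1 array at a time gave 0 to 3 higher and 0 to 2 lower over the 3 times, 57 to 110 higher at day 3, 14 to 27 higher and 37 to 52 lower at day 10, and 3 to 6 lists; without the day 3 array with activated RNA in Cy5 110 were higher, and without the day 10 array with it in Cy3 27 were higher. Within day 3 or day 10, a count with 1 array left out rests on a single array. Its dye effect is not cancelled and no same sign on a second array is required. The cause was not tested beyond these settings.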

Other observations

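Many probes for microRNA genes that lie next to each other in the genome had similar ratios, with exceptions. The pairs named here were chosen after their values were seen, and centring would move both members of a pair alike. The genes of miR-132 and miR-212 are neighbours, and probes 1org-132 and 2org-212 were at 3.74 and 3.95 at day 3 and at -0.56 and -0.40 at day 10. Probes 2org-221 and 2org-222 were at 2.19 and 2.64 at day 3 and at 2.50 and 2.68 at day 10. The genes of 1org-183 and 1org-96 lie together, at 3.87 and 3.43 at day 3 but at 0.51 and 2.23 at day 10, and miR-182 (1org-182), in the same cluster, was at 0.30 and -0.73. Probes 1org-296 and 1org-298 also differed, at 1.08 and 3.46 at day 3 and at 1.07 and -0.49 at day 10. For 1org-34a (-0.66 at day 10) and 1org-34c (4.26), ID and annotation disagree on which is the neighbour of miR-34b (1org-34b, -1.27), so that pair is either alike or far apart.

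A hypothesis from these values is that shared transcription of neighbouring genes may shape the response. The pattern was seen before its test was chosen, while the checks on background and on shared numbers were chosen before their results were seen. Of 109 probes with 1 located gene, named by the annotation or by the number in the ID, 33 pairs started within 10000 bases of each other in GRCm38.p6, and their median distance over the day 3 and day 10 log2 ratios was 0.81, against 1.96 in 10000 shuffles of the probes (permutation p = 0.00050, adjusted over 3 tests 0.00075). Pairs of 1 microRNA number do not account for it, since 30 pairs of different numbers gave 0.84 against 1.98 (permutation p = 0.0014). Among the 16 pairs in which both probes were at least 2-fold off the array median, the median distance was 1.12 against 3.19 (permutation p = 0.00020), but these were chosen by the ratios and not by signal, so probes alike because both are near background stay open. With 1org-34a and 1org-34c named by ID, chosen after seeing the data, the 33 pairs gave 0.88 against 1.97 (permutation p = 0.0013). Cross-hybridization between related sequences of different numbers, such as 17-5p and 20, may add to it and stays open, and pairs that share a probe are not independent.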
